A study of Mus musculus with 56 samples.

How the data were processed

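The series holds 56 mouse samples in 27 groups, 9 of them ChIP input controls. Per the labels, mice had sham surgery with vehicle (Sham), transverse aortic constriction with vehicle (TAC), which loads the left ventricle with pressure, TAC with JQ1, an inhibitor of the BET bromodomain proteins (TAC JQ1), or TAC with JQ1 that was later stopped (TAC JQ1 withdrawn). Single-cell RNA (scRNA) and single-cell ATAC (scATAC) libraries came from the non-cardiomyocyte cells of digested ventricles, 2 libraries per group and assay. Bulk RNA libraries came from cardiomyocytes (CM) of Sham, TAC and TAC JQ1 hearts, 3 per group. ChIP libraries for H3K27ac, a mark of active promoters and enhancers, and for HA-tagged MEOX1 came from an immortalised line of mouse cardiac fibroblasts. The line was unstimulated (Unstim) or treated with 10 ng/ml TGF-beta (TGFb). The 4 chromosome conformation (4C) and 8 nascent transcription (PROseq) samples were not analysed here. The JQ1 dose and the time of withdrawal are not given in the sources used here.

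The deposited scRNA matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 3.0.2 on mm10, per the file headers and the labels. They list all barcodes, not only called cells. The deposited scATAC matrices hold counts of transposase insertion sites per peak and barcode, with peaks called separately in each library. The labels name Cell Ranger ATAC 1.0.0 and the file headers version 1.0.1. The deposited cardiomyocyte table holds raw read counts per Ensembl gene in 37991 rows. Per the submitters' processing notes, its reads passed FastQC and were aligned with STAR 2.7.3a; the program that counted them is not given in the sources used here. Gene positions in that table are not those of mm10, so genes were matched by identifier only, and 86.6% of identifiers had a symbol. 1 row of the table, that of Ttn, was broken over 2 lines and was rejoined. The authors also deposited 2 tables with the log2 fold change and adjusted p-value of 6949 genes each. The tool behind them is not given in the sources used here, and 12 further columns in them that hold values per sample were not used here. The authors deposited 4 lists of ChIP peaks as intervals without scores, which by their names are intersections of replicates. Per the labels, the ChIP reads were aligned with Bowtie2 2.2.4; the peak caller and its threshold are not given in the sources used here.

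Cells were taken from the scRNA matrices by a rule on UMIs. A barcode was kept with at least 1 divided by 10 of the 99th percentile of the top 5000 barcodes of its library, with a floor of 500 UMIs, with at least 300 genes, and with at most 10% of mitochondrial UMIs. Doublets were scored against simulated pairs of cells within each library and removed at a rate of 0.8% per 1000 cells. Counts were scaled and log-transformed, 2000 variable genes and 30 principal components were computed with scanpy 1.11.5, and cells were clustered with leidenalg 0.10.2 (15 neighbours, resolution 1.0). Clusters took the name of the marker list with the highest score among fixed lists. Cluster 8, with 2610 cells, carried mural and endothelial genes together and kept no name. Free RNA was profiled in barcodes with at most 100 UMIs. UMIs of the fibroblasts, macrophages and endothelial cells were summed per library, since cells of 1 library are not replicates. The lymphatic endothelial cells formed a separate class.

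For scATAC, barcodes with at least 1000 counts were kept, and doublets were not removed. Peaks of the 8 libraries were merged into 86668 regions, of which the 34994 that held a peak in all 8 libraries were used. Nuclei were clustered on 30 components of a latent semantic analysis (scikit-learn 1.9.0, resolution 0.8), without 2 components that followed depth with a correlation above 0.5. Clusters were named by counts over marker genes and the 2000 bp upstream of them, and counts of fibroblast nuclei were summed per library. The length of called peaks inside a region differed between libraries, with means from 724 to 1250 bp.

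Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, all groups of an assay in 1 fit, and the quasi-likelihood test. Genes or regions with a Benjamini-Hochberg adjusted p under 0.05 were called. Values are CPM, TMM-scaled counts relative to library size, as means with SD over libraries, and log2 fold changes carry the SE from the fit in parentheses. The labels do not say that replicates are separate animals, so the p-values measure the spread between samples. Shares of cells are given as values per group and were not tested. The fixed gene lists named in the results were tested with camera and fry of limma 3.58.1 on the same design, with camera's preset correlation of 0.01 and with an estimated one. Camera's p-values were adjusted over the lists of a contrast and class. Whether a change differed between cell classes was tested in a joint fit with the library as a block. Simulated counts without group effects gave the covariance and correlation of fold changes that shared libraries alone would produce, in 20 simulations for RNA and 5 for accessibility.

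Replicates carry numbers in the labels, so pairing by number was checked before any blocked fit was seen. Deviations from the group means of libraries with the same number correlated between 0.146 and 0.545 across genes in the scRNA classes, above the 0.1 set for pairing. They correlated between -0.0292 and 0.138 in cardiomyocytes and between -0.202 and 0.0784 in scATAC. The counts of calls with the replicate number as a block are therefore printed beside the scRNA results, although the labels do not say what the numbers stand for.

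ChIP intervals that overlapped or touched were merged, shared peaks overlapped by at least 1 bp, and 1000 random placements on the same chromosomes gave the overlap by chance. Shares carry 95% Wilson intervals, which cover counting error only. Promoters were the 1000 bp either side of a transcription start site in the mm10 annotation, and a gene counted as near a peak within 10 kb. The enrichment of MEOX1 peaks in called regions and genes was tested with Fisher's exact test against all tested regions or genes, adjusted over the family. The homeobox core TAATTA was counted in the central 200 bp of peaks and in flanking windows 1 kb away.

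The groups, main tests, gene lists and the rule for named genes were fixed before the data were examined, as were most alternatives. The even called length of regions, the replicate block for gene lists and shared genes, the fit without mitochondrial genes, the class comparison of immediate early genes and the splits of cardiomyocyte samples were added later. The rule names, per contrast and class, the 6 genes with the largest positive and the 6 with the most negative fold change among called genes with at least 20 CPM in the higher group and no overlap between the libraries. It adds up to 4 members of each list with the smallest p and a fixed set of genes always given. For every gene named as risen or fallen, the libraries of the groups compared did not overlap. Chance alone separates 2 libraries from 2 with a probability of 0.333 and 3 from 3 with 0.1. For accessibility, the rule names the 5 regions with the largest gain and loss, the regions within 100 kb of the Meox1 start site and the Postn promoter.

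The test was checked on simulated counts with the observed depth and spread. It recovered 2-fold changes in 27.0% of changed genes in fibroblasts, 17.5% in macrophages, 25.5% in endothelial cells, 60.8% in cardiomyocytes and 34.3% of regions. It recovered 4-fold changes in 84.0%, 82.8%, 77.8%, 85.7% and 70.0% in the same order. False calls were 10 of 121, 8 of 107, 9 of 111, 10 of 153 and 16 of 120 calls for TAC against Sham, and 7 of 155 for TAC JQ1 against TAC in cardiomyocytes, where the threshold implies 5%. Alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, no filter or a stricter one, the replicate block, each library left out in turn, other thresholds for cells (2000 UMIs, 20% mitochondrial UMIs, doublets kept, 300 cells per library, ambient-rich genes left out), other thresholds for nuclei and regions (3000 counts, 2000 bp), and other overlaps of peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the remaining steps.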

Results

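The study followed mouse hearts through pressure overload, BET inhibition with JQ1 and withdrawal of JQ1. It measured RNA and chromatin accessibility in single non-cardiomyocyte cells, RNA in cardiomyocytes, and peaks of H3K27ac and HA-tagged MEOX1 in a line of cardiac fibroblasts. The scRNA libraries 1 and 2 held 26747681 and 28429166 UMIs in Sham, 24672890 and 27197224 in TAC, 31722785 and 32676763 in TAC JQ1, and 28593665 and 28996077 in TAC JQ1 withdrawn. The scATAC libraries 1 and 2 held 13242148 and 27773962 counts in Sham, 62588382 and 23889610 in TAC, 47449013 and 71273649 in TAC JQ1, and 81993982 and 64055271 in TAC JQ1 withdrawn. The cardiomyocyte libraries 1 to 3 held 36834574, 35701724 and 15234777 reads in Sham, 36550578, 31948359 and 32494063 in TAC, and 37135861, 38096611 and 24818425 in TAC JQ1. Mitochondrial genes took between 55.5% and 70.8% of the cardiomyocyte reads. The ChIP lists give intervals only, so the depth behind a peak is unknown.

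The scRNA libraries gave 51901 cells with a median of 2242 UMIs, of which 20082 were fibroblasts, 16893 endothelial cells, 8671 macrophages and 1378 mural cells. Fibroblasts made up 32.5 ± 2.55% of the cells in Sham, 41.2 ± 2.90% in TAC, 34.9 ± 0.354% in TAC JQ1 and 45.5 ± 2.33% in TAC JQ1 withdrawn (mean ± SD, n = 2 libraries). Macrophages made up 16.2 ± 2.19%, 26.4 ± 6.58%, 13.5 ± 4.53% and 13.2 ± 2.47% in the same order. Endothelial cells made up 37.4 ± 5.94%, 23.6 ± 9.69%, 38.4 ± 3.68% and 29.3 ± 3.11%. Dendritic cells, which present antigen, stood at 0.849 ± 0.00354% in Sham, 1.21 ± 0.262% in TAC, 0.122 ± 0.0347% in TAC JQ1 and 0.415 ± 0.00636% in TAC JQ1 withdrawn. In both TAC libraries the share of fibroblasts and of macrophages was above that of both Sham and both TAC JQ1 libraries. The scATAC nuclei gave 27.7% and 28.0% fibroblasts in the Sham libraries, 41.3% and 38.5% in TAC, 26.9% and 29.4% in TAC JQ1, and 34.7% and 38.1% in TAC JQ1 withdrawn. The shares add up to a whole, so a rise of 1 class lowers the others.

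**Figure D1:**
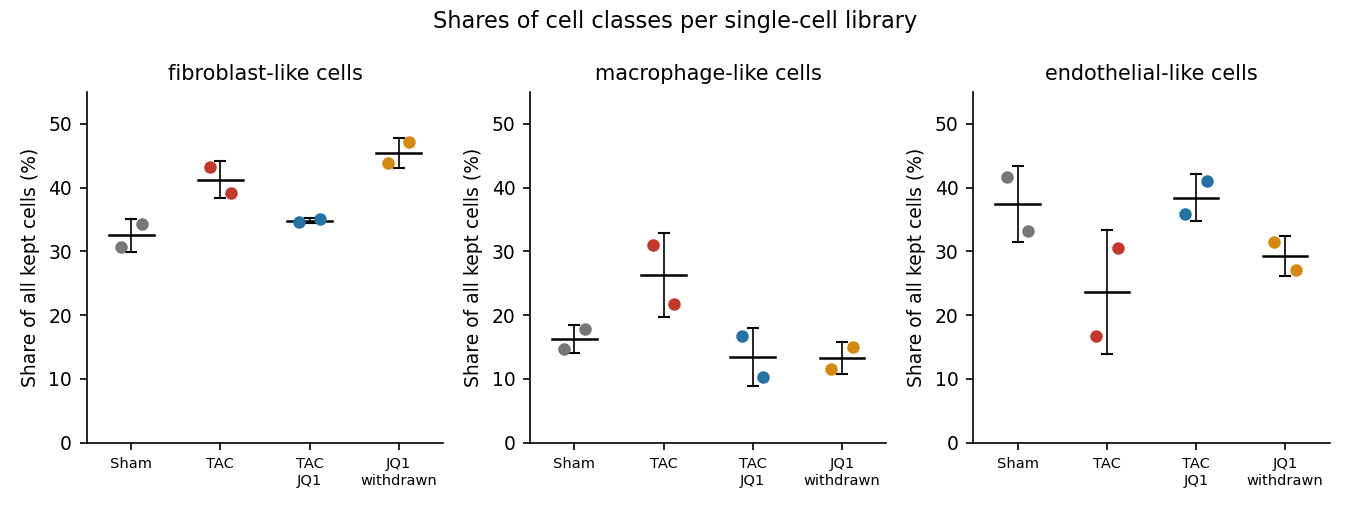
Share of fibroblasts, macrophages and endothelial cells among the kept cells of each scRNA library (y axis, % of cells) by group (x axis); points are libraries, black lines means and bars SD. Fibroblasts averaged 41.2% in TAC against 32.5% in Sham, and macrophages 26.4% against 16.2%.

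The 3 large classes spread over clusters that differed in use between groups. Fibroblasts of the Sham libraries sat mostly in cluster 1 (53.6% and 51.9%), which was also the largest cluster of TAC JQ1 fibroblasts (49.3% and 47.8%). TAC fibroblasts sat mostly in cluster 3 (68.4% and 51.3%). Macrophages were mostly in cluster 4 in TAC (67.9% and 63.9%) and in cluster 6 in TAC JQ1 (59.3% and 52.0%). Endothelial cells were mostly in cluster 0 in TAC (51.0% and 55.9%) and in cluster 5 in TAC JQ1 (73.6% and 78.6%). Summed counts of a class therefore mix a change within cells with a change in the mix of states.

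TAC against Sham asks which genes pressure overload changes in each cell class. In fibroblasts, genes of activated, matrix-producing cells rose. Postn (ENSMUSG00000027750, mm10 chromosome 3: 54361109 to 54391037), which encodes the matrix protein periostin, rose from 85.0 ± 34.5 CPM to 3340 ± 204 CPM (n = 2 per group; log2 fold change 5.30, SE 0.39, adjusted p = 0.00018). Meox1 (ENSMUSG00000001493, chromosome 11: 101877510 to 101894374), which encodes a homeobox transcription factor, rose from 136 ± 2.05 CPM to 877 ± 177 CPM (2.69, SE 0.28, adjusted p = 0.000784). Cilp (ENSMUSG00000042254, chromosome 9: 65265180 to 65280605), Comp (ENSMUSG00000031849, chromosome 8: 70373558 to 70382066) and Thbs4 (ENSMUSG00000021702, chromosome 13: 92751590 to 92794818) encode extracellular matrix proteins. Cilp rose from 82.3 ± 21 CPM to 1480 ± 331 CPM (4.17, SE 0.28), Comp from 7.39 ± 1.58 CPM to 820 ± 124 CPM (6.80, SE 0.26), and Thbs4 from 7.18 ± 1.56 CPM to 625 ± 122 CPM (6.45, SE 0.44). Spp1, which encodes osteopontin, rose from 0.42 ± 0.0393 CPM to 217 ± 47.3 CPM, and Wisp1 from 0.196 ± 0.277 CPM to 30.7 ± 0.969 CPM.

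Of the 34 matrix genes measured in fibroblasts, 15 rose with TAC and 1 fell (adjusted over the list alone, 21 and 1; camera adjusted p = 4.07e-21, and 0.0617 with an estimated correlation). Among them, Lox, which cross-links collagen, rose by 3.05 (SE 0.25) on the log2 scale, Col8a1 by 2.37 and Fn1 (ENSMUSG00000026193), encoding fibronectin, by 2.08 (SE 0.20). Col1a1 (ENSMUSG00000001506) was not called, at 633 ± 10.2 CPM in Sham and 1080 ± 267 CPM in TAC (adjusted p = 0.115), nor was the contractile actin gene Acta2 (ENSMUSG00000035783), at 19.7 ± 2.88 CPM and 39.9 ± 14.3 CPM (adjusted p = 0.133). The activated fibroblast list had 18 members higher and 1 lower out of 21 (19 and 1 adjusted over the list alone; camera adjusted p = 2.12e-87, and 0.018 with an estimated correlation). Ctgf (ENSMUSG00000019997), a matricellular growth factor gene, rose from 126 ± 5.37 CPM to 1310 ± 349 CPM (3.38, SE 0.25). Of 18 TGF-beta response genes, 8 rose and none fell (10 and 1 adjusted over the list alone; camera adjusted p = 6.22e-06, and 0.0955 with an estimated correlation), with Tgfb1 at 1.78 and Tgfb3 at 1.21. The cytokine gene Il6 rose by 3.32 (SE 0.51) and Ptgs2, which encodes an enzyme of prostaglandin synthesis, by 2.00 (SE 0.38), while Cxcl1 fell by 1.13.

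Genes of resting fibroblasts and immediate early genes went the other way. Of 20 resting fibroblast genes, 10 fell with TAC and 3 rose (13 and 5 adjusted over the list alone; camera adjusted p = 2.53e-06, and 0.129 with an estimated correlation). Efemp1 fell from 214 ± 6.51 CPM to 40.0 ± 11 CPM (-2.42, SE 0.25), Scara5 from 213 ± 5.30 CPM to 46.8 ± 14.4 CPM (-2.19, SE 0.23), and Penk, which encodes an opioid precursor, from 172 ± 16.9 CPM to 16.2 ± 2.57 CPM (-3.41, SE 0.27). Tcf21 (ENSMUSG00000045680), encoding a transcription factor of cardiac fibroblasts, fell from 239 ± 30.2 CPM to 145 ± 17.8 CPM (-0.72, SE 0.18, adjusted p = 0.0461). Immediate early genes respond to stimuli and to tissue digestion within minutes. 10 of the 20 fell with TAC and none rose (13 and 1 adjusted over the list alone; camera adjusted p = 4.8e-12, and 0.0262 with an estimated correlation), among them Btg2 by 2.12 (SE 0.17) and Dusp1 by 1.76 (SE 0.29). Of 13 interferon response genes, 1 rose, Ifit3 (6 adjusted over the list alone; camera adjusted p = 0.00238, and 0.207 with an estimated correlation). Of 11 cell cycle genes, 2 rose, Tyms and Mcm6 (median -0.0912, mean 0.202; camera adjusted p = 0.274). None of 10 BET inhibitor response genes (camera adjusted p = 0.335) and none of 13 unfolded protein response genes (adjusted p = 0.138) was called, though 4 of the latter rose with the replicate number as a block.

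Among the 12018 genes tested in fibroblasts, 399 were higher and 332 lower in TAC than in Sham, and 621 of these 731 changed by more than 1 on the log2 scale. With the replicate number as a block, 1488 were called. Without Sham 1 the count was 327, and without Sham 2 it was 306. Leaving out Sham 1 ended the call of Tgfb1 (adjusted p = 0.053). Leaving out either Sham library ended that of Ptgs2 (adjusted p up to 0.105). Those of Cxcl1 (up to 0.114) and Ifit3 (up to 0.164) ended without Sham 1, Sham 2 or TAC 1, and that of Tyms without Sham 1 (0.0887). Tcf21 kept its call only when TAC 2 was the library left out, and Mcm6 only without TAC 1 (adjusted p up to 0.283 and 0.24).

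In macrophages, Il1b (ENSMUSG00000027398), which encodes the cytokine interleukin 1 beta, rose with TAC from 160 ± 5.44 CPM to 508 ± 73.3 CPM (n = 2 per group; 1.67, SE 0.17, adjusted p = 0.0175). The chemokine gene Ccl12 rose from 295 ± 16.5 CPM to 1600 ± 75.0 CPM (2.44, SE 0.43, adjusted p = 0.0453), and Ch25h, encoding cholesterol 25-hydroxylase, from 5.56 ± 0.110 CPM to 56.8 ± 16.1 CPM (3.35, SE 0.48, adjusted p = 0.0213). Retnla, a gene of alternatively activated macrophages, fell from 1100 ± 445 CPM to 72.8 ± 39.7 CPM (-3.93, SE 0.44, adjusted p = 0.0175). The lectin genes Cd209f and Cd209g fell by 2.46 (SE 0.38) and 2.79 (SE 0.41), and Mmp9 by 2.05. Ccr2 (ENSMUSG00000049103), the chemokine receptor gene of recruited monocytes, was not called at 51.1 ± 14.4 CPM in Sham and 122 ± 10.3 CPM in TAC (1.26, SE 0.36, adjusted p = 0.222), nor were Timd4 (adjusted p = 0.274) and Lyve1 (0.305) of resident macrophages. Of 18 inflammatory cytokine genes, 2 rose, Il1b and Ptgs2 (5 adjusted over the list alone; camera adjusted p = 1.79e-09). No member was called of the resident macrophage list (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.00114), the interferon response list (3 higher; 0.000301), the monocyte-derived macrophage list (3 higher; 0.0429) or the cell cycle list (adjusted p = 6.6e-08, median 0.916). With the replicate number as a block, 2 interferon response, 3 monocyte-derived macrophage and 1 cell cycle gene rose. With an estimated correlation, none of the 5 set calls held (adjusted p = 0.222, 0.274, 0.222, 0.266 and 0.274).

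Among 10282 genes tested in macrophages, 25 were higher and 20 lower in TAC (45 in all, and 240 with the replicate number as a block). The genes called included Postn (3.27) and Ankrd1 (2.51), which fibroblasts and cardiomyocytes express. Without Sham 2 edgeR called 0 genes, with 669 at an unadjusted p under 0.05, against 113 called by DESeq2 with all libraries. The count was 24 without Sham 1, 8 without TAC 2 and 16 without TAC JQ1 1. Leaving out Sham 2 ended the calls of Il1b (adjusted p = 0.112) and Retnla (0.0746), which held without any other library. That of Ccl12 ended without Sham 1, Sham 2, TAC 1, TAC 2 or TAC JQ1 1 (up to 0.213), and that of Ch25h without Sham 1, Sham 2 or TAC JQ1 1 (up to 0.147). Those of Cd209f and Cd209g ended without Sham 2, TAC 1 or TAC 2 (up to 0.139), that of Mmp9 without these or TAC JQ1 1 (up to 0.179), and that of Ptgs2 without any Sham or TAC library or TAC JQ1 withdrawn 1 (up to 0.251).

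In endothelial cells, TAC against Sham called 10 of 11624 genes, most of them genes of other cell types. Cardiomyocyte genes fell: Tnni3 from 64.1 ± 8.16 CPM to 6.11 ± 2.7 CPM (n = 2 per group; -3.32, SE 0.36, adjusted p = 0.0256), Myh6 by 3.29, Myl3 by 2.68, Myl2 by 2.59 and Tnnt2 by 2.33. Fibroblast genes rose: Cilp from 0.782 ± 0.793 CPM to 22.9 ± 7.97 CPM (4.75, SE 0.53, adjusted p = 0.0256) and Mfap4 from 2.7 ± 0.561 CPM to 26.7 ± 2.19 CPM (3.31, SE 0.31). Thbs4, chosen after its values were seen, also rose. Vwa3a fell from 24.2 ± 1.41 CPM to 5.19 ± 0.807 CPM (-2.19, SE 0.26, adjusted p = 0.0268). Esm1 (ENSMUSG00000042379), a marker of activated endothelium, was not called at 12.4 ± 4.42 CPM and 50.1 ± 25.1 CPM (2.02, SE 0.41, adjusted p = 0.203), nor was the flow-responsive transcription factor gene Klf2 at 4670 ± 374 CPM and 2450 ± 350 CPM (-0.93, SE 0.17, adjusted p = 0.164). No member of any list was called, though with the replicate number as a block 3 immediate early genes fell, and 1 inflammatory cytokine and 1 endothelial activation gene rose. The immediate early list had 6 members lower and 1 higher adjusted over the list alone (camera adjusted p = 8.93e-08, 0.03 with an estimated correlation, and 0.137 with that and the replicate block), and the endothelial activation list 2 higher (0.032, and 0.445). The endothelial fatty acid handling list was not called (adjusted p = 0.132). Leaving out Sham 1, Sham 2 or TAC 1 left edgeR with 0 calls, with 592, 652 and 1135 genes at an unadjusted p under 0.05, and leaving out TAC JQ1 1 or TAC JQ1 2 left 3. Leaving out the genes rich in free RNA also gave 0 calls, with 587 at an unadjusted p under 0.05, against 72 by DESeq2 with all genes. With the replicate number as a block, 78 were called.

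TAC JQ1 against TAC asks which changes the BET inhibitor makes in the loaded heart. In fibroblasts, genes that TAC had raised fell. Meox1 fell from 877 ± 177 CPM to 90.4 ± 30.1 CPM (n = 2 per group; -3.28, SE 0.29, adjusted p = 0.000488), below the 136 ± 2.05 CPM of Sham. Postn fell to 415 ± 180 CPM (-3.01, SE 0.35, adjusted p = 0.00108), Comp to 92.8 ± 11.5 CPM (-3.14, SE 0.21), Cilp to 274 ± 61.9 CPM (-2.43, SE 0.26), Thbs4 to 86.1 ± 47.9 CPM (-2.86, SE 0.36) and Ctgf to 321 ± 27.7 CPM (-2.03, SE 0.23). Tagln, which encodes an actin-binding protein of contractile fibroblasts, fell from 190 ± 57.1 CPM to 18.8 ± 1.63 CPM (-3.34, SE 0.29). Among called genes with at least 20 CPM in the higher group and no overlap, the most negative changes included Ereg (-6.56), Wisp1 (-5.98), F2rl1 (-5.81) and Dio2 (-5.70). Tcf21 rose from 145 ± 17.8 CPM to 297 ± 12.2 CPM (1.03, SE 0.18, adjusted p = 0.00554), and Dpep1, of resting fibroblasts, from 437 ± 214 CPM to 2280 ± 244 CPM (2.38, SE 0.31). Hexim1, which encodes an inhibitor of the elongation factor P-TEFb and responds to BET inhibitors, rose from 28.5 ± 2.8 CPM to 95.5 ± 12.1 CPM (1.74, SE 0.21, adjusted p = 0.00129), and Brd2, encoding a BET protein, from 62.3 ± 8.29 CPM to 181 ± 9.40 CPM (1.54, SE 0.17).

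**Figure D2:**
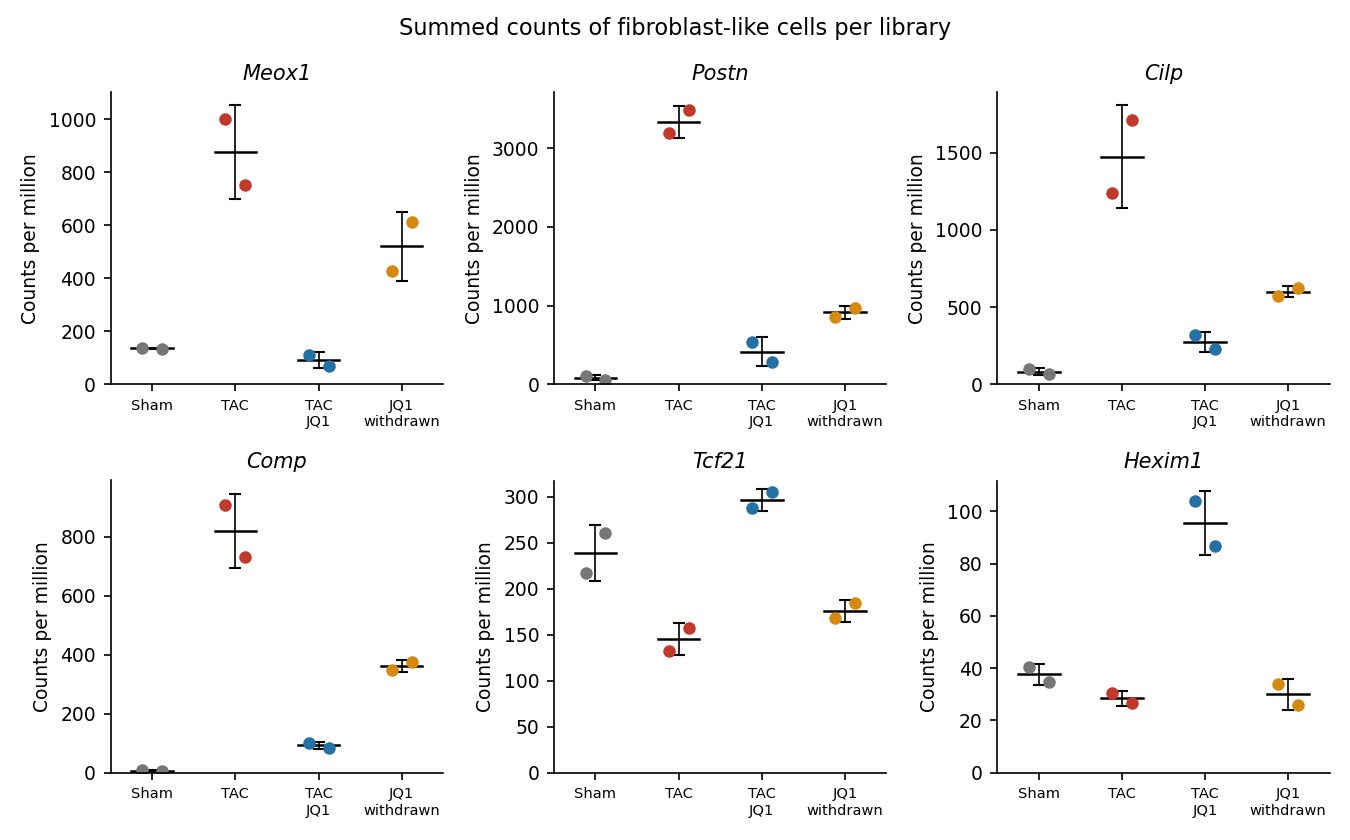
Expression of Meox1, Postn, Cilp, Comp, Tcf21 and Hexim1 in fibroblasts (y axis, TMM-scaled CPM) by group (x axis); points are scRNA libraries, black lines means and bars SD. Meox1 averaged 136 in Sham, 877 in TAC, 90.4 in TAC JQ1 and 521 in TAC JQ1 withdrawn.

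By list, 20 of 34 matrix genes fell with JQ1 and none rose (25 and 0 adjusted over the list alone; camera adjusted p = 1.92e-13, and 0.08 with an estimated correlation). They included Col12a1 by 3.28 (SE 0.47), Lox by 2.41, Fn1 by 1.29 (SE 0.20) and Col1a1 by 1.16 (SE 0.25). Of the 21 activated fibroblast genes, 18 fell (19 adjusted over the list alone; adjusted p = 5.82e-38, 0.0248 with an estimated correlation, and 0.0815 with that and the replicate block), with Acta2 at 16.1 ± 7.57 CPM after 39.9 ± 14.3 CPM (-1.31, SE 0.35, adjusted p = 0.0317). Of 20 resting fibroblast genes, 11 rose (11 adjusted over the list alone; 3.45e-07, and 0.106 with an estimated correlation), such as Scara5 by 1.81, Efemp1 by 1.80 and the complement gene C3 by 1.48. Immediate early genes rose in 15 of 20 cases (16 adjusted over the list alone; 1.38e-19, and 0.0175 with an estimated correlation), with Btg2 at 2.58 (SE 0.18), Atf3 at 2.47 and Dusp1 at 2.41. Of 10 BET inhibitor response genes, 4 rose (4 adjusted over the list alone; 0.000376, and 0.0583 with an estimated correlation). The inflammatory cytokine list split, with 4 members higher and 5 lower (6 and 5 adjusted over the list alone; 0.566). In it Cxcl1 rose from 158 ± 41.8 CPM to 850 ± 5.73 CPM, while Il6 fell by 3.23 and Ptgs2 by 1.70. Of 18 TGF-beta response genes, 5 fell and 1 rose (8 and 2 adjusted over the list alone; 0.0987), and of 13 unfolded protein response genes, 5 fell (5 adjusted over the list alone; 0.0708), among them the chaperone gene Hspa5 by 1.32.

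JQ1 against TAC called 2112 of 12018 genes in fibroblasts, 900 higher and 1212 lower, and 1424 of them changed by more than 1 on the log2 scale. With the replicate number as a block the count was 3638. Without TAC JQ1 1 the count was 753, and without TAC JQ1 2 it was 503. Leaving out TAC JQ1 2 ended the calls of Tcf21 (adjusted p = 0.0611), Col1a1 (0.135) and Fn1 (0.0504), and leaving out either TAC JQ1 library that of Hspa5 (up to 0.0654). That of Acta2 ended without TAC 1 or TAC JQ1 2 (up to 0.216), and that of Ptgs2 without TAC 1 or either TAC JQ1 library (up to 0.105). Of the genes higher in TAC, 312 were lower with JQ1, and 188 of those lower in TAC were higher with JQ1. Independent lists would share 40.2 and 24.9 genes, but both contrasts share the TAC libraries, which favours such counts. Across genes, both fold changes had a covariance of -0.480 and a correlation of -0.6144, against -0.0722 and -0.46 in 20 simulations without group effects. The 312 became 168 without Sham 1, 157 without Sham 2, 199 without TAC JQ1 1 and 143 without TAC JQ1 2.

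In macrophages, Ccr2 fell with JQ1 from 122 ± 10.3 CPM to 2.71 ± 0.679 CPM (n = 2 per group; -5.45, SE 0.49, adjusted p = 0.000427). Ccl12 fell by 4.39 (SE 0.47), Ccr1 by 4.23 and Cx3cr1 by 4.04. The MHC class II gene H2-Aa fell from 3800 ± 692 CPM to 633 ± 121 CPM (-2.58, SE 0.22, adjusted p = 0.000427), H2-Ab1 by 2.54 and H2-Eb1 by 2.62. Il1b fell from 508 ± 73.3 CPM to 127 ± 2.19 CPM (-2.00, SE 0.18), while Il6 rose from 6.47 ± 2.47 CPM to 32 ± 10.3 CPM (2.33, SE 0.34, adjusted p = 0.00372) and Cxcl1 by 2.13 (SE 0.35). The linker and core histone genes Hist1h1c and Hist1h2bc rose by 2.52 and 2.74, Hexim1 by 1.59 (SE 0.22) and Brd2 by 1.62 (SE 0.20). Of 12 monocyte-derived macrophage genes, 5 fell (5 adjusted over the list alone; camera adjusted p = 6.42e-09, 0.049 with an estimated correlation, and 0.0727 with that and the replicate block). Of 14 resident macrophage genes, 2 rose, Vsig4 by 1.09 and Cd163 by 0.70 (2 adjusted over the list alone; 0.0902). Of 18 inflammatory cytokine genes, 4 rose and 2 fell (8 and 3 adjusted over the list alone; 0.0226, and 0.656 with an estimated correlation). Immediate early genes rose in 3 of 20 cases (5 adjusted over the list alone; 7.84e-06, and 0.175) and BET inhibitor response genes in 3 of 10 (3 adjusted over the list alone; 0.00248, and 0.104).

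JQ1 called 896 of 10282 genes in macrophages, 283 higher and 613 lower, and 1783 with the replicate number as a block. Without TAC 1 the count was 546, without TAC JQ1 1 it was 185, and without TAC JQ1 2 it was 157. Cxcl1 lost its call without TAC JQ1 2 (adjusted p = 0.0541), Hist1h1c without TAC JQ1 1 (0.0517), Vsig4 without TAC 1 or either TAC JQ1 library (up to 0.234), and Cd163 without those or Sham 2 (up to 0.191). Of the 25 genes higher in TAC, 20 were lower with JQ1, against 1.49 for independent lists, a count that the shared TAC libraries favour. Across genes, both fold changes had a covariance of -0.119 and a correlation of -0.297, against -0.0711 and -0.448 in simulations without group effects.

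**Figure D3:**
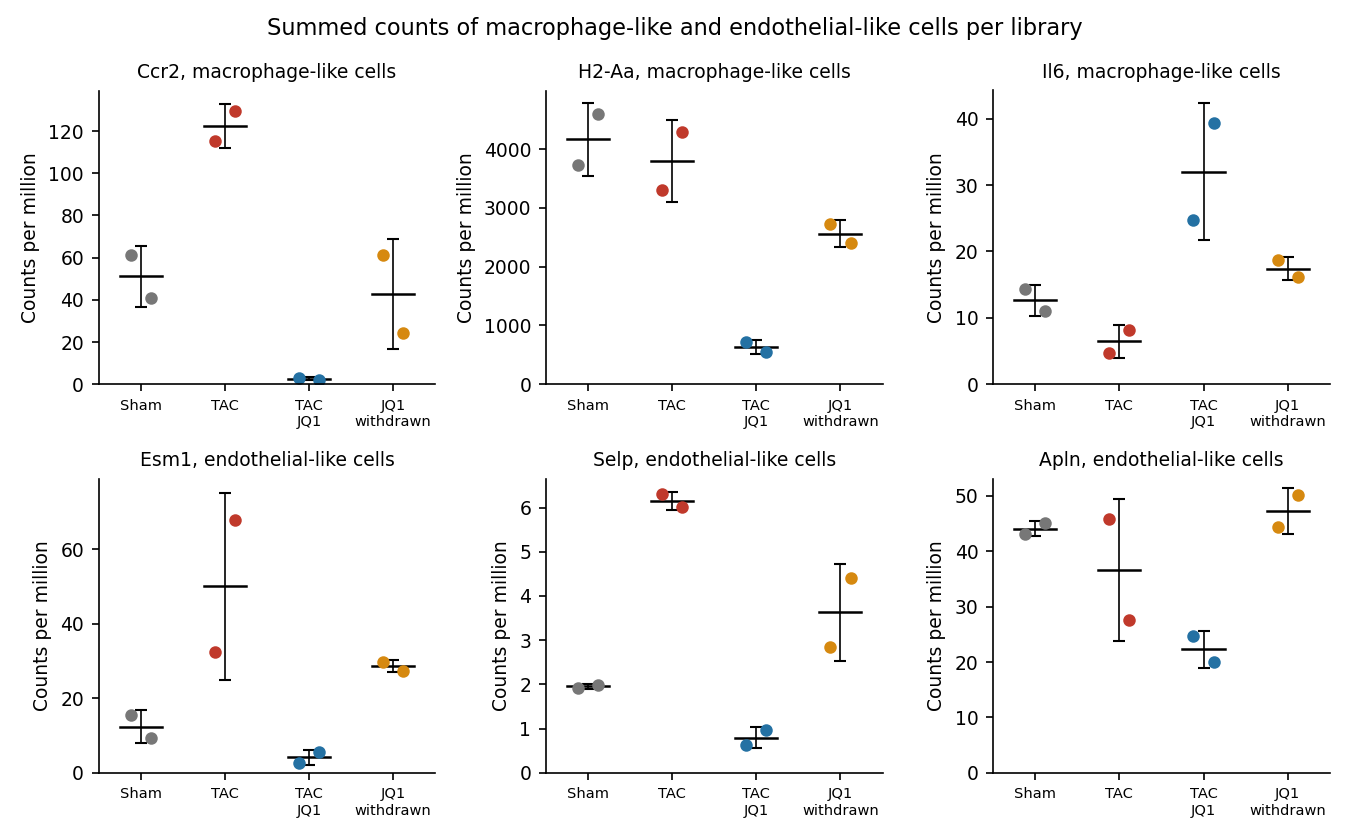
Expression of Ccr2, H2-Aa and Il6 in macrophages and of Esm1, Selp and Apln in endothelial cells (y axis, TMM-scaled CPM) by group (x axis); points are scRNA libraries, black lines means and bars SD. Ccr2 averaged 122 in TAC and 2.71 in TAC JQ1, and Esm1 50.1 and 4.10.

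In endothelial cells, Esm1 fell with JQ1 from 50.1 ± 25.1 CPM to 4.10 ± 1.99 CPM (n = 2 per group; -3.59, SE 0.46, adjusted p = 0.00481), and Selp, encoding the leukocyte adhesion molecule P-selectin, from 6.15 ± 0.204 CPM to 0.797 ± 0.248 CPM (-2.88, SE 0.48, adjusted p = 0.011). Nepn fell from 34.4 ± 20.1 CPM to 1.5 ± 0.517 CPM (-4.55, SE 0.49), Sost, a Wnt inhibitor gene, by 5.37, Il6 by 4.87 and Cysltr1, a leukotriene receptor gene, by 3.44. Cadm1, encoding an adhesion molecule, rose from 6.74 ± 0.0304 CPM to 58.8 ± 5.77 CPM (3.12, SE 0.23, adjusted p = 0.00385), Klf2 from 2450 ± 350 CPM to 4830 ± 250 CPM (0.98, SE 0.17, adjusted p = 0.0139) and Hexim1 from 30.3 ± 8.82 CPM to 92.9 ± 8.75 CPM (1.63, SE 0.31, adjusted p = 0.0161). The angiogenic peptide gene Apln (-0.70, adjusted p = 0.131) and the fatty acid binding protein gene Fabp4 (0.44, adjusted p = 0.304) were not called. The cardiomyocyte gene Tnni3, named above among genes of other cell types, rose from 6.11 ± 2.7 CPM to 34 ± 10.5 CPM (2.41, SE 0.36). Immediate early genes rose in 10 of 20 cases (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.21e-09, 0.022 with an estimated correlation, and 0.118 with that and the replicate block). Of 15 endothelial activation genes, 2 fell (3 lower and 1 higher adjusted over the list alone; 0.0477, and 0.39), and of 10 BET inhibitor response genes 2 rose (3 higher and 1 lower adjusted over the list alone; 0.11). None of 10 fatty acid handling genes was called (0.986). The count was 1152 of 11624 genes, 393 higher and 759 lower, and 2494 with the replicate number as a block. Without TAC JQ1 1 it was 1, without TAC JQ1 2 edgeR called 0, with 2093 at an unadjusted p under 0.05 and 1009 by DESeq2 with all libraries, and without TAC 2 and TAC JQ1 withdrawn 2 it was 649 and 767. Each gene named here as risen or fallen lost its call without TAC JQ1 1 and without TAC JQ1 2, Cadm1 only without the latter (adjusted p = 0.0518). Hexim1 also lost it without TAC 2 (up to 0.11), and the others reached adjusted p values up to 0.112.

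TAC JQ1 withdrawn against TAC JQ1 asks which of these changes return once the inhibitor is stopped. In fibroblasts Meox1 rose again, from 90.4 ± 30.1 CPM to 521 ± 129 CPM (n = 2 per group; 2.53, SE 0.28, adjusted p = 0.00419), and Comp from 92.8 ± 11.5 CPM to 362 ± 20.2 CPM (1.97, SE 0.20). Cilp rose from 274 ± 61.9 CPM to 600 ± 35.1 CPM (1.13, SE 0.25, adjusted p = 0.0276), Thbs4 by 1.46 (SE 0.34), Wisp1 by 4.33, the tendon transcription factor gene Scx by 3.51 and Fblim1, which encodes a protein of cell-matrix adhesions, by 3.04 (SE 0.24). Postn was not called, at 415 ± 180 CPM and 915 ± 81.9 CPM (1.14, SE 0.33, adjusted p = 0.0652), nor were Ctgf (0.60, adjusted p = 0.137), Col1a1 (0.52, 0.226), Fn1 (0.09, 0.825) and Acta2 (1.05, 0.0979). Hexim1 fell to 30.0 ± 5.77 CPM (-1.67, SE 0.21), Brd2 by 1.47, Hist1h2bc by 3.14 (SE 0.27) and Tcf21 from 297 ± 12.2 CPM to 176 ± 11.9 CPM (-0.75, SE 0.18, adjusted p = 0.0347). Of 21 activated fibroblast genes, 13 rose and none fell (18 adjusted over the list alone; camera adjusted p = 1.89e-18), and of 34 matrix genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; 0.00872), or 8 and 1 with the replicate number as a block. Immediate early genes fell in 13 of 20 cases (16 adjusted over the list alone; 3.56e-17), resting fibroblast genes in 2 of 20 (3 adjusted over the list alone; 0.00965), interferon response genes in 4 of 13 (5 adjusted over the list alone; 0.00292) and inflammatory cytokine genes in 4 of 14 with 1 higher (5 and 2 adjusted over the list alone; 0.0449). With an estimated correlation the immediate early list held (0.0182), and the activated fibroblast (0.0813), matrix (0.44), resting fibroblast (0.402), interferon response (0.296) and inflammatory cytokine lists (0.296) did not.

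Withdrawal called 963 of 12018 genes in fibroblasts, 642 higher and 321 lower, and 2298 with the replicate number as a block. Without TAC JQ1 2 the count was 5, without TAC JQ1 1 it was 195, and without TAC JQ1 withdrawn 1 and 2 it was 271 and 288. Of the 41 named genes called, 39 lost their call without TAC JQ1 2, among them Meox1 (adjusted p = 0.0562) and Comp (0.0569), which held without any other library. Fblim1 and Hist1h2bc held whichever library was left out. Cilp lost its call without any of the 4 libraries of the contrast (up to 0.235), Thbs4 without TAC JQ1 2 or either withdrawn library (up to 0.177), and Tcf21 without those, TAC JQ1 1 or either Sham library (up to 0.222). Of the 312 genes higher in TAC and lower with JQ1, 130 were higher on withdrawal. They were chosen for low values in TAC JQ1 libraries that the withdrawal contrast uses again, which favours a rise. Across all genes, the fold changes with JQ1 and on withdrawal had a covariance of -0.640 and a correlation of -0.8625, against -0.0816 and -0.529 in simulations without group effects.

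In macrophages, withdrawal raised Ccr2 from 2.71 ± 0.679 CPM to 42.7 ± 26.1 CPM (n = 2 per group; 3.92, SE 0.50, adjusted p = 0.00374), H2-Aa from 633 ± 121 CPM to 2560 ± 226 CPM (2.02, SE 0.22) and Il1b from 127 ± 2.19 CPM to 292 ± 24.9 CPM (1.20, SE 0.17). Gpr34, a lipid receptor gene, rose by 3.94 and the growth factor gene Igf1 by 1.17 (SE 0.26). Hist1h2bc fell by 2.94, Hexim1 by 1.42 (SE 0.23) and Brd2 by 1.4. Of 12 monocyte-derived macrophage genes, 5 rose (5 adjusted over the list alone; camera adjusted p = 3.07e-05, and 0.109 with an estimated correlation). The count was 559, 415 higher and 144 lower, and 1291 with the replicate number as a block. Without TAC JQ1 1 it was 130, without TAC JQ1 2 it was 28, and without TAC JQ1 withdrawn 1 and 2 it was 183 and 168. Hist1h2bc held whichever library was left out. Ccr2, H2-Aa, Gpr34 and Brd2 lost their call without TAC JQ1 2 (adjusted p up to 0.0557), Il1b and Hexim1 without TAC JQ1 1, TAC JQ1 2 or TAC JQ1 withdrawn 2 (up to 0.0992), and Igf1 without any of the 4 (up to 0.276).

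In endothelial cells, withdrawal raised Esm1 from 4.10 ± 1.99 CPM to 28.6 ± 1.59 CPM (n = 2 per group; 2.76, SE 0.46, adjusted p = 0.0127), Apln from 22.3 ± 3.34 CPM to 47.3 ± 4.16 CPM (1.09, SE 0.26, adjusted p = 0.0392), Selp by 2.11 (SE 0.49), Nepn by 3.94 and Ptprr, a phosphatase gene, by 2.84. Cadm1 fell by 2.72 (SE 0.22), the clock gene Cry2 by 2.73, Klf2 by 0.92 and Lpl, encoding lipoprotein lipase, by 1.12 (SE 0.19). Immediate early genes fell in 7 of 20 cases (7 adjusted over the list alone; camera adjusted p = 4.25e-06, 0.0481 with an estimated correlation, and 0.224 with that and the replicate block), and endothelial activation genes rose in 3 of 15 (3 higher and 1 lower adjusted over the list alone; 0.196). The count was 900, 592 higher and 308 lower, and 2267 with the replicate number as a block. Without TAC JQ1 1 or TAC JQ1 2 edgeR called 0 genes, with 1899 and 1844 at an unadjusted p under 0.05 and 777 by DESeq2 with all libraries. Without TAC JQ1 withdrawn 1 and 2 the count was 114 and 110. Each gene named here lost its call without TAC JQ1 1 and without TAC JQ1 2. Esm1, Klf2 and Lpl lost it without either withdrawn library too (up to 0.153), as did Apln and Selp, which also lost it without either Sham library (up to 0.256).

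In cardiomyocytes, TAC raised genes of the stress response. Acta1 (ENSMUSG00000031972), which encodes skeletal actin, a fetal isoform in the heart, rose from 67.1 ± 14.8 CPM to 986 ± 148 CPM (n = 3 per group; 3.88, SE 0.19, adjusted p = 9.22e-08). Ankrd1, encoding a stretch-responsive sarcomere protein, rose from 270 ± 144 CPM to 1510 ± 430 CPM (2.49, SE 0.31, adjusted p = 0.000802), and Xirp2, also of the sarcomere, from 451 ± 57.0 CPM to 1990 ± 648 CPM (2.14, SE 0.21). Rcan1 (ENSMUSG00000022951), a target of calcineurin signalling, rose from 21.1 ± 1.61 CPM to 92.1 ± 26.8 CPM (2.13, SE 0.18), and the natriuretic peptide gene Nppb from 42.3 ± 5.72 CPM to 112 ± 51.8 CPM (1.4, SE 0.23, adjusted p = 0.00379). Nppa was not called, at 159 ± 175 CPM and 550 ± 376 CPM (1.79, SE 0.66, adjusted p = 0.134), nor were Myh6 (-0.21, adjusted p = 0.485) and the calcium pump gene Atp2a2 (-0.41, adjusted p = 0.104). Tgfb2 rose from 2.73 ± 0.161 CPM to 17.0 ± 9.10 CPM (2.65, SE 0.28), and the transcription factor gene Myc by 2.01 (SE 0.30). Acaa2, of fatty acid oxidation, fell from 139 ± 18.4 CPM to 74.9 ± 8.75 CPM (-0.89, SE 0.12, adjusted p = 0.00137), the potassium channel gene Kcnd2 by 0.90 (SE 0.15) and Hopx by 0.97.

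By list, 9 of 15 cardiomyocyte stress genes rose with TAC and none fell (12 adjusted over the list alone; camera adjusted p = 1.33e-35, and 0.0325 with an estimated correlation). Of 20 fatty acid oxidation genes, 5 fell and 1 rose, Pdk4 (12 and 1 adjusted over the list alone; 1.57e-05, and 0.0754). None of 20 oxidative phosphorylation genes was called (11 lower adjusted over the list alone; 1.04e-05, and 0.408). Of 32 matrix genes, 6 rose, among them Col4a1 by 0.95 (18 adjusted over the list alone, camera adjusted p = 2.55e-10, and 0.361). Of 13 activated fibroblast genes, 5 rose and 1 fell (9 and 2 adjusted over the list alone, 2.56e-05, and 0.337). Thbs4, of that list, rose by 2.73. Of 13 unfolded protein response genes, 3 fell (6 lower and 1 higher adjusted over the list alone, 0.0468, and 0.438). Of 16 genes of contraction and calcium handling, 1 rose and 1 fell (3 and 3 adjusted over the list alone; 0.507), and in the glycolysis list 1 rose and 1 fell (3 and 2; 0.17). The count was 662 of 13929 genes, 406 higher and 256 lower, and 254 of them changed by more than 1 on the log2 scale. Without Sham 1 it was 422, without Sham 2 it was 271, and without TAC 3 it was 237. Pdk4 lost its call without Sham 2, Sham 3 or TAC 3 (adjusted p up to 0.064). Myh7, called at 1810 ± 706 CPM against 1050 ± 51.9 CPM (0.79, SE 0.21, adjusted p = 0.0479), lost it without any library but TAC 1 (up to 0.181). The libraries also hold RNA of other cells, with fibroblast markers at a mean of 99.8 ± 35.1 CPM in Sham, 136 ± 61.0 CPM in TAC and 59.7 ± 24.9 CPM in TAC JQ1, against 105000, 90200 and 103000 CPM of cardiomyocyte markers.

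In cardiomyocytes, JQ1 lowered some stress genes and left others uncalled. Acta1 fell from 986 ± 148 CPM to 432 ± 58.5 CPM (n = 3 per group; -1.19, SE 0.17, adjusted p = 0.00148), above the 67.1 ± 14.8 CPM of Sham, and Rcan1 fell to 28.6 ± 4.59 CPM (-1.68, SE 0.18, adjusted p = 0.000129). Ankrd1 (1090 ± 167 CPM; -0.46, SE 0.29, adjusted p = 0.42), Nppb (63.5 ± 4.74 CPM; -0.82, SE 0.23, adjusted p = 0.0523) and Nppa (-1.10, adjusted p = 0.374) were not called. Tgfb2 fell to 5.30 ± 0.233 CPM (-1.69, SE 0.27), and the Z-disc gene Synpo2l by 1.65 (SE 0.26). Hexim1 rose from 4.94 ± 0.985 CPM to 23.9 ± 0.572 CPM (2.27, SE 0.14, adjusted p = 2.05e-06), Brd2 from 22.2 ± 1.28 CPM to 66.1 ± 13 CPM (1.57, SE 0.14), Tcap, of the Z-disc, by 1.47 (SE 0.27) and Acaa2 to 112 ± 0.917 CPM (0.57, SE 0.12, adjusted p = 0.0138). Of 15 stress genes, 6 fell (9 adjusted over the list alone; camera adjusted p = 6.83e-09, and 0.216 with an estimated correlation), and of 20 fatty acid oxidation genes 2 rose (7 adjusted over the list alone; 0.000593, and 0.173). Of 32 matrix genes, 9 fell (24 adjusted over the list alone, 3.21e-12, and 0.22). The fibroblast totals above went the same way, at 136 ± 61.0 in TAC and 59.7 ± 24.9 in TAC JQ1. Of 10 BET inhibitor response genes, 2 rose (3.28e-06, and 0.0585). The count was 776 of 13929 genes, 290 higher and 486 lower. Without TAC 2 it was 467, and without TAC JQ1 1, 2 and 3 it was 373, 379 and 309. Acaa2 lost its call without any of the TAC JQ1 libraries (up to 0.0578). Of the genes higher in TAC, 115 were lower with JQ1, against 14.2 for independent lists, a count that the shared TAC libraries favour. Across genes, both fold changes had a covariance of -0.0854 and a correlation of -0.2857, against -0.0585 and -0.499 in simulations without group effects. The 115 became 64 without Sham 2, 50 without TAC 3, and 56, 62 and 50 without TAC JQ1 1, 2 and 3.

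**Figure D4:**
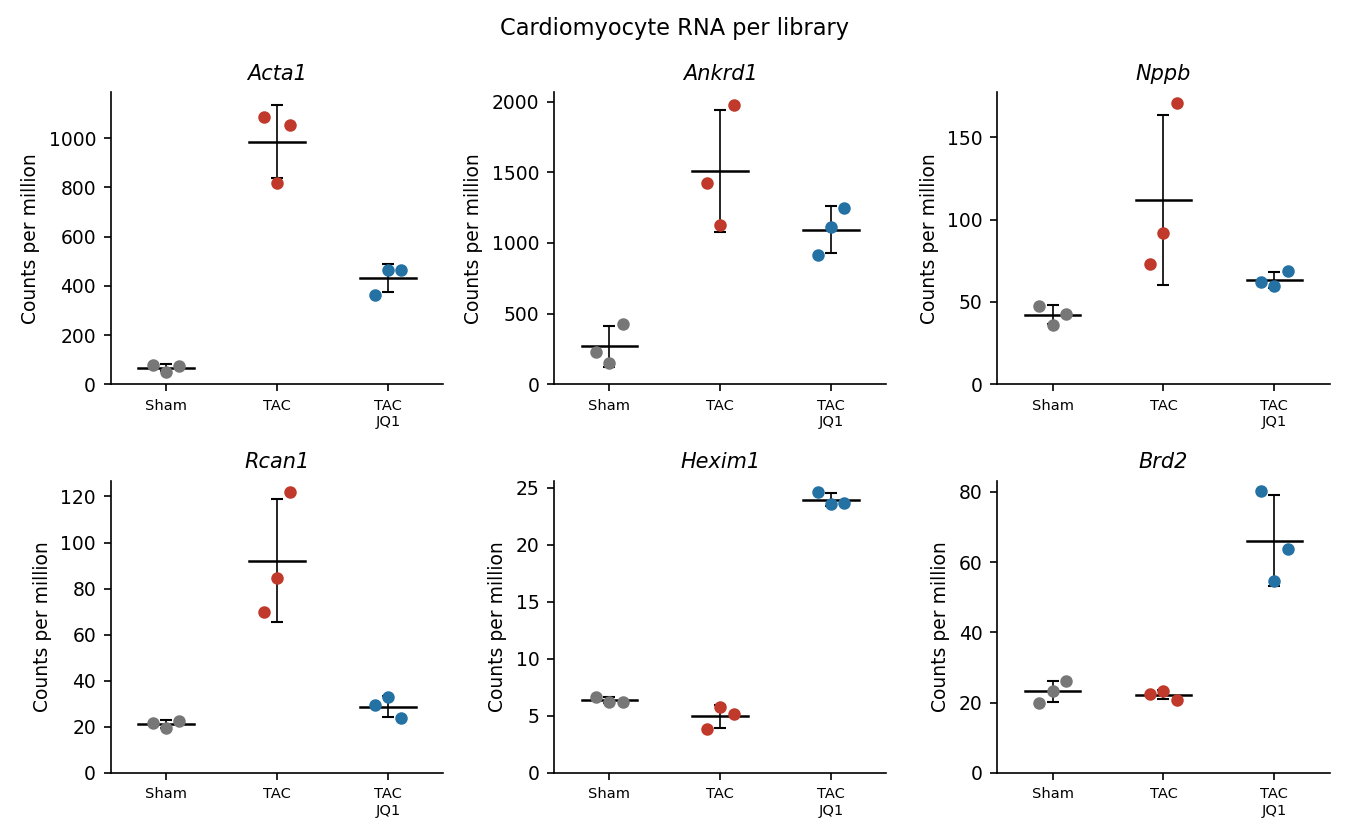
Expression of Acta1, Ankrd1, Nppb, Rcan1, Hexim1 and Brd2 in cardiomyocytes (y axis, TMM-scaled CPM) by group (x axis); points are bulk RNA libraries, black lines means and bars SD. Acta1 averaged 67.1 in Sham, 986 in TAC and 432 in TAC JQ1.

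The authors' tables of cardiomyocyte genes called 547 genes for TAC against Sham and 618 for TAC JQ1 against TAC. Of the 6708 genes matched, 394 were called there and here in each contrast, 145 and 200 were called in the authors' table alone, and 32 and 13 here alone. Across genes, which are not independent replicates, the fold changes correlated with 0.9996 and 0.9998, and 95.8% and 95.1% had the same sign.

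Accessibility asks where the chromatin of fibroblasts opens or closes along the same treatments. Of 24 regions tested within 100 kb of the Meox1 start site, 6 gained accessibility with TAC and 0 lost it. With JQ1, 5 lost it. All 5 losses ended without either TAC JQ1 library (adjusted p up to 0.283). The region at chromosome 11: 101820520 to 101821627, 72.7 kb from the Meox1 start site and nearer to that of Etv4 (35.1 kb), rose from 6.18 ± 0.528 CPM in Sham to 26.6 ± 4.23 CPM in TAC (n = 2 per group; 2.13, SE 0.24, adjusted p = 0.00189) and fell to 10.5 ± 1.28 CPM with JQ1 (-1.35, SE 0.22, adjusted p = 0.00946). After withdrawal it was not called (1.01, SE 0.21, adjusted p = 0.168). Its gain with TAC held whichever library was left out, as did that at 101831635 to 101832559 (1.42, uncalled with JQ1). Inside the gene, the region at 101885012 to 101887061 rose from 15.2 ± 2.65 CPM to 36.5 ± 3.62 CPM (1.29, SE 0.25, adjusted p = 0.014), with a mean called length of 636 bp in Sham and 1412 bp in TAC, and fell by 1.31 with JQ1 (adjusted p = 0.0133). Its gain ended without TAC 1 (adjusted p = 0.0543). The region at 101880878 to 101882920 rose from 81.8 ± 4.49 CPM to 123 ± 9.97 CPM (0.60, SE 0.14, adjusted p = 0.0258) and fell by 0.99. The Meox1 promoter region, 101892688 to 101894890, rose from 11.4 ± 3.92 CPM to 24.8 ± 5.94 CPM (1.08, SE 0.25, adjusted p = 0.0254), with called lengths of 652.5 bp and 1118 bp, and was not called with JQ1 (-0.29, adjusted p = 0.485). These last gains ended without 5 and 6 of the 8 libraries in turn (up to 0.0915 and 0.117). The Postn promoter region (chromosome 3: 54357519 to 54360152) was not called, at 27.7 ± 5.03 CPM in Sham and 41.2 ± 4.18 CPM in TAC (0.56, SE 0.16, adjusted p = 0.0605).

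**Figure D5:**
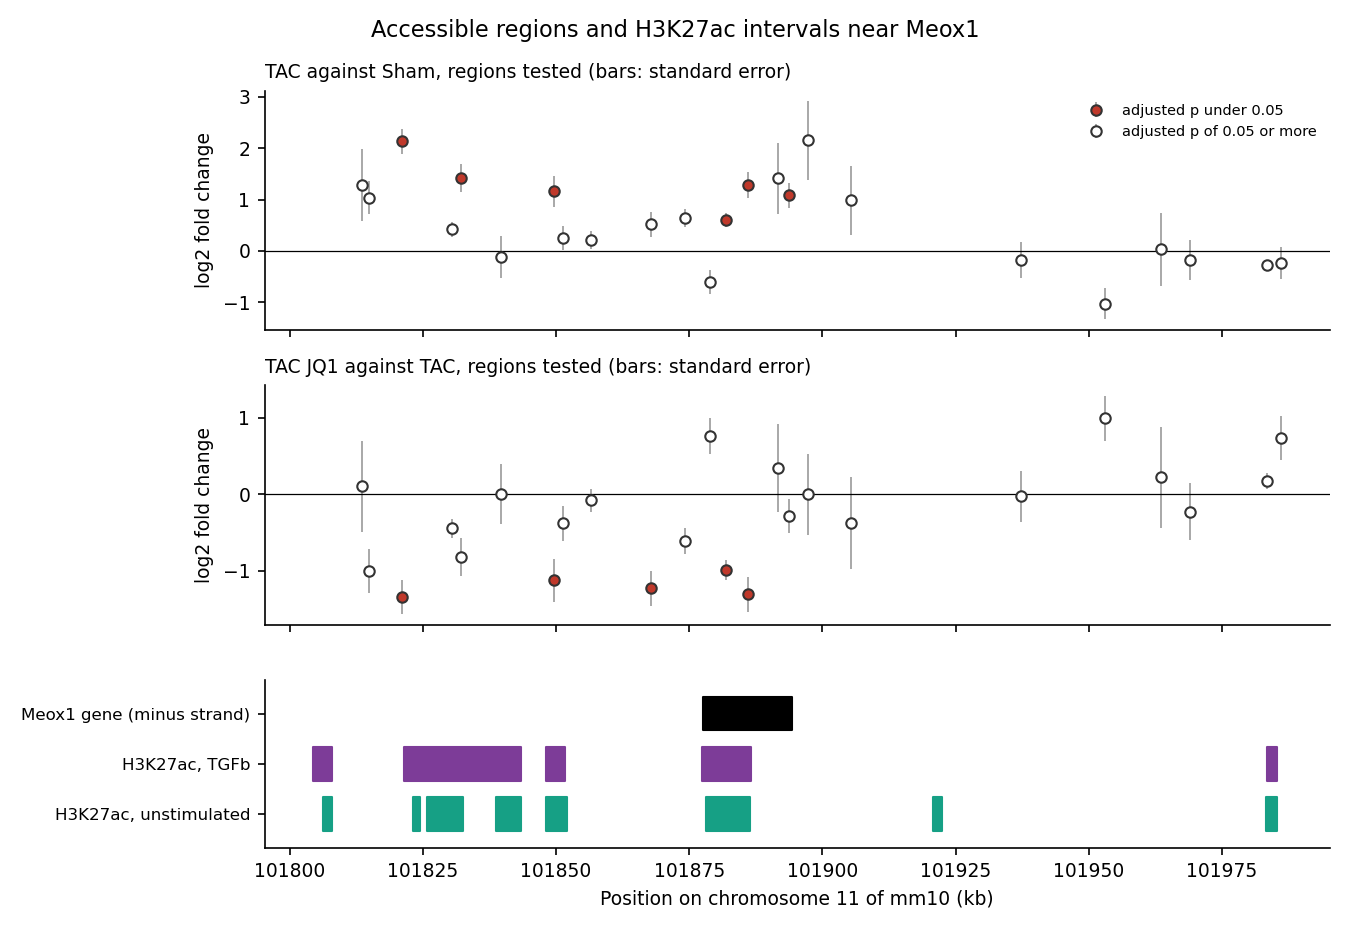
Regions of fibroblast accessibility around Meox1 on mm10 chromosome 11 (x axis, position in kb) with their log2 fold change and SE (y axis) for TAC against Sham and for TAC JQ1 against TAC, above the gene and the H3K27ac peaks of the fibroblast line. Filled points have an adjusted p under 0.05, open points 0.05 or more. The region 72.7 kb from the start site had 2.13 with TAC against Sham and -1.35 with TAC JQ1 against TAC.

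Among the largest gains with TAC, a region 4.49 kb from the Plekhg5 start site (chromosome 4: 152076987 to 152078711) rose from 0 counts in Sham to 20.9 ± 4.50 CPM, at least 88.7-fold higher against 3 counts over the Sham libraries. A region 51.1 kb from Cd44, a receptor gene for hyaluronan (chromosome 2: 102849829 to 102850520), was at least 23.9-fold higher. Both bounds rest on counts inside the peaks called in each library. Regions higher in TAC had longer called peaks in TAC, with a median log2 length ratio of 0.532 against 0.15 over all regions. The largest losses had short called peaks in the TAC libraries, such as the region 28.6 kb from Mgst3 (chromosome 1: 167422411 to 167423113), which fell from 33.0 ± 9.74 CPM to 0.964 ± 0.866 CPM (-5.41, SE 0.51) with a mean called length of 70.5 bp in TAC and 652 bp in Sham. With JQ1, the region 21.2 kb from the phosphatase gene Dusp5 (chromosome 19: 53507225 to 53507935) fell from 18.8 ± 1.29 CPM to 2.33 ± 0.730 CPM (-3.03, SE 0.30), and that 35.2 kb from the protease inhibitor gene Timp3 (chromosome 10: 86264405 to 86265157) rose by 4.97, and both calls ended without TAC JQ1 2 (adjusted p = 0.0615 and 0.0522). Across regions, the ratio of called lengths correlated with the fold change at 0.47, 0.649 and 0.523 in the 3 contrasts. Only insertion sites inside a library's own called peaks were counted, so a shorter called peak lowers the count of its region by construction. How much of each fold change came from this, and whether more accessible regions give longer peaks, was not tested.

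Of 34692 regions tested, TAC raised 1869 and lowered 1741 against Sham. JQ1 raised 910 and lowered 1263 against TAC. Of the regions higher in TAC, 769 were lower with JQ1, against 68 for independent lists, a count that the shared TAC libraries favour. Across regions, both fold changes had a covariance of -0.295 and a correlation of -0.5031, against -0.0722 and -0.46 in simulations without group effects. Cluster 3 held 5.4% and 9.2% of fibroblast nuclei in Sham, 3.3% and 3.4% in TAC and 67.8% and 78.3% in TAC JQ1. On withdrawal it held 46.8% and 38.1%. It was deeper than cluster 0 (relative counts 1.9 and 0.94), and depth's role was not tested. Summed counts may mix changes within nuclei and in states. Withdrawal raised 1 region against TAC JQ1 and lowered 0 by edgeR, with 2945 at an unadjusted p under 0.05 and 337 called by DESeq2. It lies 9.59 kb from Spon2, a matrix protein gene (chromosome 5: 33228048 to 33229489; 24.6 ± 3.00 CPM and 60.6 ± 3.46 CPM; 1.31, SE 0.12, adjusted p = 0.0467). For TAC against Sham the 3610 calls became 2113, 2074, 2176 and 2170 without TAC JQ1 1, TAC JQ1 2, TAC JQ1 withdrawn 1 and TAC JQ1 withdrawn 2. For JQ1 against TAC the 2173 calls became 231 without TAC JQ1 1 and 0 without TAC JQ1 2, with 4093 at an unadjusted p under 0.05. They became 1072 without either withdrawn library, and 3933 and 3999 without Sham 1 and Sham 2. For withdrawal they became 99 and 109 without Sham 1 and Sham 2 and 2 without either TAC library. They became 0 without either TAC JQ1 or either withdrawn library, with 1582, 1466, 1547 and 1456 regions at an unadjusted p under 0.05.

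The ChIP lists ask where H3K27ac changes and MEOX1 sits in fibroblasts with and without TGF-beta. The H3K27ac lists held 25323 intervals with TGFb and 22446 in Unstim, none of them on chromosome 1. Of the TGFb intervals, 20540 (81.1%, 95% interval 80.6 to 81.6) overlapped an Unstim interval, 5.05 times the overlap of random placements. The MEOX1-HA lists held 4299 merged intervals with TGFb and 4839 in Unstim, of which 2046 (47.6%, 46.1 to 49.1) and 2042 (42.2%, 40.8 to 43.6) were shared. Outside chromosome 1, 3678 of 4040 MEOX1-HA intervals with TGFb (91.0%, 90.1 to 91.9) and 3868 of 4528 in Unstim (85.4%, 84.4 to 86.4) lay in H3K27ac intervals of the same condition. Promoters held the centre of 2.86% of the MEOX1-HA intervals with TGFb and 3.31% in Unstim. The lists carry no scores, and no test between the conditions was run.

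At Meox1, the H3K27ac list with TGFb held 1 interval of 22000 bp (chromosome 11: 101821400 to 101843399), where the Unstim list held 3, at 101823200 to 101824399, 101825800 to 101832599 and 101838800 to 101843399. The interval at 101920800 to 101922399 was in the Unstim list only. At Acta2 the pattern was reversed, with 1 Unstim interval of 38000 bp where the TGFb list held intervals of 22400 and 8600 bp. No MEOX1-HA interval lay within 100 kb of Meox1. In Unstim, an interval lay at the Acta2 promoter (chromosome 19: 34255095 to 34255294) and another 9.89 kb from its start site. At Ctgf, both lists held an interval 5.91 kb from the start site, and Unstim held another over it (chromosome 10: 24595292 to 24595484). With TGFb, an interval lay 7.03 kb from Col1a1 (chromosome 11: 94928998 to 94929197). Neither list held any within 10 kb of the start sites of Postn, Cilp, Comp, Thbs4, Fn1 or Tcf21. The homeobox core TAATTA was present in 6.35% of the MEOX1-HA intervals with TGFb and 5.92% of their flanks (odds ratio 1.08, Fisher's exact test, adjusted p = 0.348). In Unstim it was present in 8.10% and 6.61% (odds ratio 1.24, Fisher's exact test, adjusted p = 0.00226).

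Of the 1869 regions higher in TAC, 237 (12.7%) held a MEOX1-HA interval of the TGFb list, against 2.92% of the others. The odds ratio was 4.84 (two-sided Fisher's exact test, adjusted p = 6.92e-70). Of 1741 lower regions, 22 (1.26%) held one (odds ratio 0.347). Of the 1263 regions lower with JQ1, 151 (12%) held one (odds ratio 4.22, adjusted p = 1.3e-40), and of the 910 higher with JQ1, 8 (0.879%; odds ratio 0.244). With the Unstim list, the odds ratios were 3.36 for the regions higher in TAC (adjusted p = 1.1e-37), 0.587 for the lower ones, 2.37 for those lower with JQ1 (adjusted p = 2.93e-12) and 0.979 for those higher with JQ1 (adjusted p = 1). Among fibroblast genes, 47 of 387 higher in TAC (12.1%) had an interval of the TGFb list within 10 kb, against 5.01% of the others (odds ratio 2.62, adjusted p = 1.85e-07), and 88 of 1174 lower with JQ1 (7.5%) against 5.0% (adjusted p = 0.000991). As 769 regions and 312 genes lower with JQ1 rose with TAC, these tests overlap. The genes lower in TAC (6.92%, adjusted p = 0.243), higher with JQ1 (6.02%, 0.317), and higher (6.67%, 0.16) or lower on withdrawal (7.28%, 0.164) did not pass. The Unstim list passed for none of the 6 sets. It had 8.27% against 5.65% for genes higher in TAC (adjusted p = 0.0534) and 6.64% against 5.63% for those lower with JQ1 (0.209).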

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

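The comparison of immediate early genes between cell classes and the splits of the cardiomyocyte samples are tests chosen only after the result was seen. Fibroblasts, macrophages and endothelial cells of the same libraries differed in how they changed, by a joint edgeR fit that tests the difference itself. Between fibroblasts and macrophages, 641 of 8414 genes differed for TAC against Sham, 1192 for TAC JQ1 against TAC and 257 for withdrawal. Between fibroblasts and endothelial cells, 799, 1319 and 595 of 9253 genes differed, and between macrophages and endothelial cells, 95, 328 and 242 of 8589. Meox1 rose more with TAC in fibroblasts than in endothelial cells (difference -2.05 for endothelial minus fibroblast, adjusted p = 1.13e-06). In both macrophages and endothelial cells, Btg2 (2.28 and 1.51) and Dusp1 (1.97 and 1.35) had a more positive change with TAC than in fibroblasts.

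Genes of other cell types were called in endothelial cells and macrophages for TAC against Sham. In endothelial cells, free RNA accounted for a median of 71.0% of the counts of the 10 genes called, and for over 50% in 9 of them, so Tnni3, Myh6, Cilp and Thbs4 may follow the free RNA of the libraries and not the endothelial cells. This share was computed for TAC against Sham only. Vwa3a, with 1.29%, argues against this for that gene alone. In macrophages the median over the 45 genes called was 0.713%, which argues against free RNA as the source of the set, with 4 genes over 50%, Postn, Cilp, Tnni3 and Cxcl12. Doublets that escaped removal stay open for both, and no biological explanation was tested.

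Regions that opened with TAC in fibroblasts held MEOX1-HA peaks of the cultured line more often than other regions, tested here with the TGFb list. Within 84 strata of region width and mean accessibility the odds ratio was 4.75 (95% interval 4.07 to 5.55), which argues against wide or strongly accessible regions as the source. By the calls of the main fit, it was 5.23 among regions with an even called length (3.33 to 8.2, 24 of 200 regions against 190 of 7472). Fitted alone, the regions of even length gave more calls higher in TAC, for which no odds ratio was computed. Within H3K27ac peaks of the line the odds ratio was 4.52 (3.85 to 5.32, 216 of 1214 against 883 of 19330). These values argue against uneven peak calling, and against an equal preference for all H3K27ac regions of the line, as the source. Promoters and distal regions were not tested apart, and promoters held the centre of only 2.86% of the TGFb intervals. A preference for distal active regions therefore stays open. As a hypothesis found and tested on the same data, MEOX1 may bind regions that open under pressure overload, though the tagged protein was measured in culture and not in these hearts.

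Immediate early genes were higher with JQ1 in fibroblasts, where 15 of 20 rose. Handling during digestion that moved all cells of a library alike is a candidate cause. Against it, 13 of the 20 changed more in fibroblasts than in macrophages of the same libraries by the test of the difference (median difference 1.05) and 1 less, and against endothelial cells 13 changed more and 2 less (0.965). Handling that acts on fibroblasts more than on other classes stays open, as does an effect of JQ1 itself. The same genes were less positive in fibroblasts than in macrophages with TAC (10 of 20, with 2 more positive, median difference -0.964) and on withdrawal (8 of 20, with 0 more positive, -0.840).

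The cardiomyocyte samples of a contrast make 10 splits of 3 against 3, too few for a share under 0.05. For TAC against Sham, 1 split gave as many genes, the real one with 662, and the highest of the other splits gave 0 by edgeR, with between 374 and 1124 genes at an unadjusted p under 0.05. For TAC JQ1 against TAC, 1 split did, the real one with 776, and the highest of the other splits gave 0, with between 257 and 778.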

How the results depend on the processing

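The even called length for regions, the replicate block in the counts of shared genes and in the tests of gene lists, and the cardiomyocyte fit without mitochondrial genes are tests chosen only after the data were seen. The even length turned the balance of regions for TAC against Sham from 1869 higher and 1741 lower to 449 and 499. Among the named genes, 9131 of 10265 comparisons of a gene and an alternative kept their side of the threshold, 795 lost a call, 339 gained one and none of the called ones changed sign, while 31 uncalled ones did. Among the named regions, 1302 of 1419 comparisons kept their side, 78 lost a call, 38 gained one and 35 uncalled ones changed sign. 1 turned: the region at chromosome 11: 101962783 to 101964386, uncalled for TAC against Sham at 0.03, was called at -2.33 without TAC 1 (adjusted p = 0.0435) and stood at 0.78 without TAC 2 (0.234). The cause was not tested. The gene lists were rerun with the replicate block only, and those of cardiomyocytes not at all. With RLE scaling 587 of 592 kept their side, with the DESeq2 Wald test 533 of 592, without a filter 495 of 592 and with 300 cells per library 353 of 421.

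Without a filter on low counts, edgeR called 1323 genes in fibroblasts for TAC against Sham and 1837 for withdrawal. It called 358, 1524 and 1099 in macrophages and 206, 1978 and 1690 in endothelial cells for TAC against Sham, JQ1 and withdrawal, and 1365 and 1322 in cardiomyocytes for the first and second of these. DESeq2 called 113 genes in macrophages and 72 in endothelial cells for TAC against Sham, and 3419 and 337 regions for JQ1 and withdrawal. The cause was not tested. With 300 cells per library, fewer counts remained, and the calls were 389, 797 and 218 in fibroblasts, 446 and 276 in macrophages for JQ1 and withdrawal, and 0 (429 at an unadjusted p under 0.05), 243 and 118 in endothelial cells. The depth of a class thus limits its count. For TAC against Sham in endothelial cells, edgeR called 0 genes with a minimum of 2000 UMIs (597 at an unadjusted p under 0.05) and 0 without the genes rich in free RNA (587). With the 6 libraries of the contrast alone, which are fewer samples, 347 cardiomyocyte genes were called for TAC against Sham.

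With the replicate block, which treats libraries of the same number as paired, the calls were 1488, 3638 and 2298 in fibroblasts, 240, 1783 and 1291 in macrophages, and 78, 2494 and 2267 in endothelial cells. The genes higher in TAC and lower with JQ1 in fibroblasts became 578. Regions lower or higher with JQ1 became 1221 and those with withdrawal 0 (2451 at an unadjusted p under 0.05, 337 by DESeq2). Of the 592 results of named genes, 503 kept their side and 89 gained a call, and of the 96 of named regions, 89 kept their side and 7 lost a call. Of 81 gene list results, 76 kept their side, the inflammatory cytokine list of fibroblasts lost its call on withdrawal (camera adjusted p = 0.0666 after 0.0449), and 4 gained one. These were the unfolded protein response in fibroblasts with JQ1 (0.0255) and, in endothelial cells, the BET inhibitor response with JQ1 (0.0498), the interferon response on withdrawal (0.00522) and the unfolded protein response on withdrawal (0.049). None of the 4 passed with an estimated correlation (0.567, 0.492, 0.348 and 0.601). With that correlation, the activated fibroblast list lost its call with JQ1 (0.0815), the monocyte-derived macrophage list with JQ1 (0.0727), and the immediate early list lost it in endothelial cells in all 3 contrasts (0.137, 0.118 and 0.224). What the numbers stand for is not given, so the cause was not tested.

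With regions whose called length was even between libraries, 948 of 7672 regions were called for TAC against Sham (449 higher, 499 lower), 1059 for JQ1 (481, 578) and 110 for withdrawal (69, 41). Fewer regions were tested there, among them 1 of the 24 around Meox1 and none of those called. The 1 region of withdrawal became 0 with RLE scaling (2945 at an unadjusted p under 0.05), with a filter of 5 CPM (2836), with at least 3000 counts per nucleus (2898) and with regions up to 2000 bp (2521). The cardiomyocyte genes higher in TAC and lower with JQ1 numbered 345 by the sign of the JQ1 change alone and 47 with both changes of at least 1 on the log2 scale, against 115, by construction.

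With a minimum of 2000 UMIs per cell, fibroblasts made up 39.1% in TAC JQ1 and 41.8% in TAC JQ1 withdrawn, macrophages 24.7%, 33.9%, 18.6% and 21.9% in Sham, TAC, TAC JQ1 and TAC JQ1 withdrawn, and endothelial cells 24.0%, 14.0%, 26.3% and 19.8% in the same order. With up to 20% mitochondrial UMIs, fibroblasts made up 34.0% in TAC JQ1 and macrophages 19.1% in Sham. The cause was not tested. With a reciprocal overlap of peaks, 52.6% and 59.3% of the H3K27ac intervals (TGFb and Unstim) and 42.4% and 37.7% of the MEOX1-HA intervals were shared. Reciprocal overlap left 0.0% of MEOX1-HA intervals in H3K27ac in both conditions, by construction, since the former are far shorter. Among the wider intervals alone, the shares were 75.3% and 78.9% for H3K27ac, 30.6% for MEOX1-HA in Unstim, and 76.3% and 67.2% for MEOX1-HA in H3K27ac.

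Each library was also left out, and a library then alone in its group is assumed to vary like the others. For TAC against Sham, JQ1 and withdrawal the calls ranged from 306 to 769, 503 to 2035 and 5 to 1441 in fibroblasts. They ranged from 0 (669 at an unadjusted p under 0.05) to 56, 157 to 787 and 28 to 666 in macrophages. In endothelial cells they ranged from 0 (592, 652 and 1135) to 11, 0 (2093) to 1049 and 0 (1899 and 1844) to 1212. In cardiomyocytes they ranged from 237 to 639 and 309 to 1013, and for regions from 2074 to 5233, 0 (4093) to 3999 and 0 (between 1456 and 1582) to 109. The genes shared between TAC and JQ1 ranged from 143 to 326 in fibroblasts and 50 to 156 in cardiomyocytes. In Sham, TAC, TAC JQ1 and TAC JQ1 withdrawn, the share of fibroblasts ranged from 30.7% to 34.3%, 39.2% to 43.3%, 34.6% to 35.1% and 43.8% to 47.1%. That of macrophages ranged from 14.7% to 17.8%, 21.7% to 31%, 10.3% to 16.7% and 11.5% to 15%, and that of endothelial cells from 33.2% to 41.6%, 16.8% to 30.5%, 35.8% to 41% and 27.1% to 31.5%.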

Other observations

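Il6 took opposite directions with JQ1 in fibroblasts and macrophages. It fell in fibroblasts from 30.1 ± 15.6 CPM to 3.15 ± 2.2 CPM (n = 2 per group; -3.23, SE 0.50) and rose in macrophages (2.33, SE 0.34), and the difference of 5.66 between the classes passed edgeR's test (adjusted p = 7.93e-05). In endothelial cells it fell (-4.87). The chaperone gene Hspa5 fell in fibroblasts and was not called in the other two classes, with a change more positive by 1.47 in macrophages (adjusted p = 0.000289) and by 1.18 in endothelial cells (adjusted p = 0.000296). Its call in fibroblasts ended without TAC JQ1 1 or TAC JQ1 2 (adjusted p up to 0.0654). Hexim1 rose in all 3 classes, with differences from fibroblasts of -0.12 in macrophages (adjusted p = 0.624) and -0.08 in endothelial cells (adjusted p = 0.811). Brd2 rose less in endothelial cells than in fibroblasts (difference -0.68, adjusted p = 0.00262).

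In cardiomyocytes, TAC also raised Uck2, of pyrimidine salvage, from 8.03 ± 1.20 CPM to 39.7 ± 16.2 CPM (n = 3 per group; 2.31, SE 0.23, adjusted p = 0.000137) and the actin regulator gene Enah from 42.1 ± 1.80 CPM to 146 ± 49.4 CPM (1.80, SE 0.18, adjusted p = 0.000157). JQ1 lowered the protease gene Adam19 from 26.2 ± 3.66 CPM to 6.32 ± 2.54 CPM (-2.05, SE 0.32, adjusted p = 0.00215) and Shroom3 by 1.59 (SE 0.18), and raised Cited2, which encodes a transcriptional coregulator, from 30.7 ± 2.94 CPM to 98.2 ± 18.9 CPM (1.68, SE 0.18, adjusted p = 0.000129). Amd1 and Amd2 rose together by 1.86 and 1.79, and as near-identical copies they share reads.

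The genes of some rarer cell classes were not tested. Schwann cells made up 0.646 ± 0.103% of the cells in Sham, 0.147 ± 0.0676% in TAC, 0.531 ± 0.309% in TAC JQ1 and 0.327 ± 0.113% in TAC JQ1 withdrawn (n = 2 libraries). T or NK cells averaged 0.612%, 0.995%, 0.328% and 0.429% in the same order, lymphatic endothelial cells 1.34%, 1.57%, 1.77% and 1.54%, and mesothelial cells 1.01%, 0.610%, 0.725% and 0.675%.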
